A study of Mus musculus with 25 samples.

How the data were processed

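Crosslink sites of SRSF7 and of its tagged variants were mapped in P19 cells by iCLIP and piCLIP in 25 libraries. Group and replicate number of every library were taken from the sample titles, and no library was left without a group. Replicate numbers in the file headers differ from those in the titles for several libraries (mutZn 3 has 1 and both WT 3 and WT 4 have 3, for example), and the titles were used. The piCLIP libraries called IgG carry that name in their titles, while their labels list anti-EGFP as the antibody. The submitters' design text states 2 to 3 biological replicates for each GFP-tagged protein, so the spread between libraries of a group was read as biological replicate error. WT 3 and WT 4 share a sequencing run and a replicate number in the headers, so whether they are separate biological replicates is not settled. Where libraries of a group are not separate cultures, the adjusted p-values are too small. Every control (no UV, IgG or no antibody) and the anti-SRSF7 library of WT cells had 1 library, so values of those groups have no replicate check.

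The deposited library files hold 1 score for each crosslinked nucleotide. Per the file headers, this score is the number of cDNAs at the position on mouse genome build mm9 with annotation Ensembl 59, and the minus sign marks the minus strand. The values checked here were whole numbers of both signs with no zero. The piCLIP files carry another result type in their headers than the iCLIP files. Per the submitters' processing notes, CASAVA 1.4 was used. The aligner and the removal of PCR duplicates are not given in the sources used here. Per the file headers, the authors also kept as peaks those positions whose cDNA score passed 100 permutations within a 15 nt neighbourhood at a false discovery rate of 0.05, on scores summed over replicates for WT, mutZn, D27aa and the piCLIP immunoprecipitates. Peak scores were therefore used only to filter peaks within a list.

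Absolute values of the scores were summed per library and strand in windows of 5000 nt, since no genome or annotation of mm9 was used here. Windows are named by mm9 coordinates, no gene, exon or intron is assigned to them, and 1 window can hold parts of several genes. CPM values are window sums scaled to the total of all windows of the library (per 1e+06 events). The no-UV libraries are shallow: 2 events are 22.5 CPM for WT and 30.0 CPM for mutZn, and 1 event is 28.6 CPM for D27aa. A few events can therefore place a window of a no-UV library above the UV level. Events on unplaced contigs were left out of the windows. Coordinates are 1-based.

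Quasi-likelihood tests with edgeR had been planned, but the signed score is not a plain count column and edgeR and DESeq2 were not used. Window sums were instead tested with a negative binomial quasi-likelihood test written in R 4.3.3. This test used scaling factors from a trimmed mean of log ratios (30% of the ratios and 5% of the mean levels trimmed at each end), a dispersion trend from the Cox-Reid adjusted profile likelihood, quasi-dispersions moderated with squeezeVar of limma 3.58.1 and never set below 1, and an F test with Benjamini-Hochberg adjustment. A window was tested when it reached the CPM equal to 10 events at the median library total in as many libraries as the smallest replicated group and 15 events in total. The adjusted p threshold was 0.05. All adjusted p-values in the text come from this limma-moderated test unless limma-voom is named. The replacement test was chosen after the unit of the files was known, and limma-voom was added as a second tool for all 7 comparisons after the data had been examined. The fits used the 7 UV anti-GFP libraries together, the 4 piCLIP immunoprecipitates, the 7 UV anti-SRSF7 libraries together, or the 5 libraries of the antibody comparison, with group as the term.

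The test was also tested on simulated data with known changes. The comparisons had already been run once on the real libraries when this simulation was written. The test recovered 71.6% of windows changed 2-fold, 89.6% of those changed 4-fold and 95.5% of those changed 8-fold for mutZn against WT (36173 windows). For D27aa against WT (36173 windows) the shares were 7.46%, 56.7% and 72.7%, and for anti-SRSF7 against anti-GFP (9899 windows) they were 11.9%, 61.2% and 77.3%. For RRM against GFP (441 windows) they were 2.04%, 12.2% and 30.6%. For poly against mono (264 windows) no changed window was recovered at 2-fold, 4-fold or 8-fold. In these simulations 16 of 187 calls were false for mutZn against WT, 9 of 100 for D27aa against WT, 8 of 108 for anti-SRSF7 against anti-GFP and 1 of 23 for RRM against GFP.

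The windows named in the text follow a rule fixed before the data were examined. Among windows past the threshold with a mean of at least 20 events per library, and with all libraries of one group above all of the other in CPM, the 8 largest log2 fold changes in each direction were taken. The parts of the rule that need gene names were not applied. The first 3 windows of each direction, a number set later, were recomputed under each alternative in which they were still tested, so windows that fell below the filter of an alternative have no value there. Stretches of adjacent called windows and the strongest windows of each group were chosen after their values were seen. Where a group had no event in a window, the fold is a lower bound against 3 events over the libraries of that group. Where it had 1 to 3 events, the ratio of pooled CPM is given with its exact 95% counting interval. Shares of single lists carry Wilson 95% intervals. Intervals and bounds cover counting error only. Log2 fold changes carry standard errors (SE) and CPM values standard deviations (SD).

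Peak lists were compared with bedtools 2.31.1 on the same strand with at least 1 shared nucleotide. Replicates were compared by a chi-square of window sums per degree of freedom, here called the dispersion index, in windows with at least 20 events in the pair. An index of 1 is sampling noise. Same-nucleotide sharing between 2 libraries was measured over 96 pairs of libraries as the number of positions shared at the same nucleotide over the mean number found 1 or 2 nt away, outside the strongest windows. In a simulation with 20% of positions copied the ratio was 1.74 and the estimate 16.6%, and with none copied the ratio was 1.02. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

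The file headers place the libraries in 6 sequencing runs. Run 1 held all piCLIP libraries. Run 2 held GFP_OE 3, RRM_OE 3, the anti-SRSF7 no-UV library and the no-antibody library, and run 3 held the other anti-SRSF7 libraries. Run 4 held WT noUV, mutZn noUV and mutZn 3, run 5 held WT 2 and D27aa 1, and run 6 held WT 3, WT 4, mutZn 4, D27aa 2 and D27aa noUV. Run was added as a block, and each comparison was repeated within the run that held both groups, as alternatives added after the data were examined. Run 6 held 1 mutZn and 1 D27aa library, so within it, as wherever a group was left with 1 library, that library was assumed to vary like those of the other groups. Both mutZn libraries shared 1 barcode, as did both D27aa libraries and both RRM_OE libraries, so barcode and group cannot be told apart there.

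The alternatives were median-of-ratios scaling, library totals alone, no filter on low windows, each position counted once, libraries thinned to the shallowest, fits of only the 2 groups compared, windows above their control left out, each replicate left out and the replicate number as a block. Gene list tests, shares of transcript regions, pentamer frequencies and the share of the SRSF7 locus had been planned and were not run, since they need a genome or an annotation of mm9. Deposited peak lists of the control libraries were not used in the comparisons.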

Results

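SRSF7 is a serine/arginine-rich RNA-binding protein that takes part in pre-mRNA splicing. Its crosslink sites were mapped in P19 cells, a mouse embryonal carcinoma line, by iCLIP. In this assay UV light links protein to RNA in living cells, the protein is immunoprecipitated with its RNA, and reverse transcription tends to stop beside the crosslinked nucleotide, so that each cDNA marks 1 crosslink event. Cells overexpressing GFP-tagged SRSF7 were studied with an anti-GFP antibody for the WT protein (3 libraries) and for the variants labelled mutZn (2) and D27aa (2), each with 1 library without UV. An anti-SRSF7 antibody gave products labelled GFP_OE (2), endo_OE (2) and RRM_OE (2) from overexpressing cells and endo_WT (1) from WT cells, with 1 library without UV and 1 without antibody. The piCLIP libraries, from monosomal and polysomal fractions, comprised 2 immunoprecipitates and 1 IgG control each.

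Depth differed widely between libraries. WT replicates 2, 3 and 4 held 221746, 1099389 and 3952779 events, mutZn replicates 3 and 4 held 11782376 and 6436730, and D27aa replicates 1 and 2 held 376870 and 388768. The anti-SRSF7 libraries of overexpressing cells held 17763 to 471705 events and endo_WT 211496. The piCLIP immunoprecipitates held 18357 to 52553 events. The no-UV libraries held 89070 events for WT, 66690 for mutZn and 34947 for D27aa, which was 5.07%, 0.732% and 9.13% of the mean of the matched UV libraries. The WT mean rests on WT 4, and the WT no-UV total was 2.25% of WT 4 and 40.2% of WT 2. Of the positions of the D27aa no-UV library 28.3% were also positions of WT 4, at 5.168 times the level 1 or 2 nt away, so its values, the 9.13% included, are not a settled background of D27aa. The IgG library held 2.73% of the mean of the immunoprecipitates in the monosomal fraction and 53.9% in the polysomal fraction, where IgG is the name in the titles and the labels list anti-EGFP for these libraries, so what they control for is not settled. For anti-SRSF7, the no-UV library held 0.598% and the no-antibody library 1.03% of the mean of GFP_OE, and against GFP_OE 3 alone the shares were 1.41% and 2.43%.

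**Figure D1:**
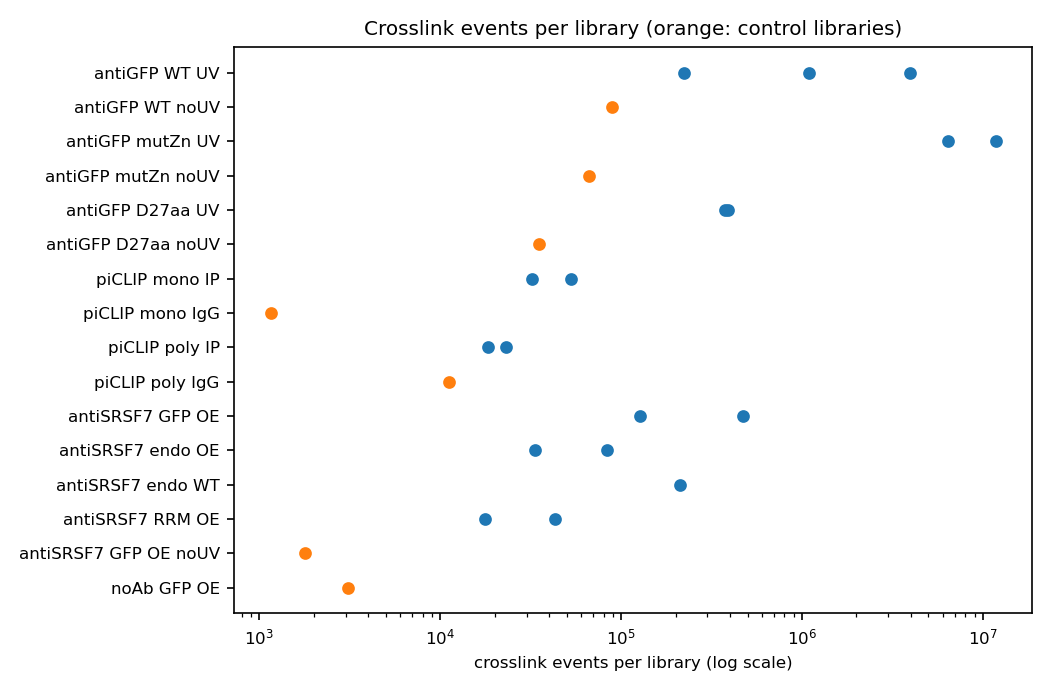
Crosslink events per library on a log axis, 1 point per library, with control libraries in orange. The mutZn libraries lie at 6436730 and 11782376 events, above every other library, and the IgG library of the monosomal fraction lies lowest at 1153.

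The comparison of mutZn with WT asks where crosslink events of the variant were more or less frequent than those of the unchanged protein. RNA levels were not among the values used here. In all comparisons of the variants, a difference in CPM is therefore not separated from a difference in RNA abundance between the cells. Long stretches differed in both directions. On the plus strand of chromosome 12 (110780001 to 110990000), 42 adjacent windows were all higher in mutZn, with 4958 ± 55.0 CPM in mutZn (SD, n = 2), 1172 ± 753 in WT (n = 3) and 2622 ± 125 in D27aa (n = 2). On the minus strand of chromosome 15 (65920001 to 66120000), 40 windows together held 1399 ± 24.1 CPM in mutZn and 415 ± 22.2 in WT, a ratio of 3.37. In the opposite direction, 40 windows on the minus strand of chromosome 17 (63035001 to 63235000) held 450 ± 4.35 CPM in mutZn and 916 ± 383 in WT, and 16 windows on the plus strand of chromosome 14 (47500001 to 47580000) held 264 ± 1.22 and 537 ± 17.5. Within sequencing run 6 the 4 ratios of mutZn to WT were 3.06, 3.36, 0.394 and 0.485. The no-UV libraries showed signal in the same stretches, 3856 CPM for mutZn and 2562 for WT on chromosome 12 and 1366 and 1011 on chromosome 15 in the higher stretches, and 495 and 517 on chromosome 17 and 345 and 315 on chromosome 14 in the lower ones.

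Among single windows, 3 adjacent ones on the minus strand of chromosome 15 (75725001 to 75740000) stood out for mutZn, with 1359 mutZn events against 5 WT events. The first of them (75725001 to 75730000) held 22.2 ± 0.906 CPM in mutZn and no event in WT, so it was at least 39.0-fold higher (adjusted p = 1.98e-12). The WT no-UV library held 4 events in the 3 windows (44.9 CPM) and D27aa 99.6 ± 20.7 CPM. On the plus strand of chromosome 15, the windows 87900001 to 87905000 and 87905001 to 87910000 held 9.37 ± 0.160 and 5.84 ± 0.0938 CPM in mutZn and no WT event, at least 16.5-fold and 10.3-fold higher (adjusted p = 2.42e-07 and 1.06e-04). The WT no-UV library held 22.5 CPM (2 events) in the second of these windows and no event in the first, and the mutZn no-UV library held 0 CPM in both. The bounds rest on the depth of WT 4, and without it they were at least 9.77-fold, 4.12-fold and 2.57-fold. The largest decrease lay on the plus strand of chromosome 12 (12260001 to 12265000), with 0.255 ± 0.360 CPM in mutZn and 119.5 ± 6.43 in WT, a log2 fold change of -8.49 ± 0.66 (SE, adjusted p = 2.75e-22). On the plus strand of chromosome 14, the window 20915001 to 20920000 held 2 mutZn and 160 WT events, a ratio of WT to mutZn of 276 (95% counting interval 75.3 to 2302, adjusted p = 3.89e-18), and the next window (20920001 to 20925000) had a log2 fold change of -6.67 ± 0.79 (adjusted p = 9.32e-15). All 6 mutZn events of the chromosome 12 window and all 4 of the last window lay in mutZn 3, and without mutZn 4 the log2 fold changes were -7.89 and -6.04. In these 3 lower windows the mutZn no-UV library held no event and the WT no-UV library 44.95, 11.2 and 22.5 CPM. Within run 6 the log2 ratios of the 16 windows named by the rule were 3.68 to 5.55 for the 8 higher and -7.86 to -4.00 for the 8 lower ones, with the direction fixed by the rule itself.

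Of 36173 windows tested between mutZn and WT, 6824 passed the threshold, 3401 higher and 3423 lower in mutZn. Adjacent windows are not independent, and these windows formed 2471 higher and 2541 lower stretches. After thinning to equal depth, the dispersion index was 0.95 between mutZn 3 and 4 and 1.18 between WT 3 and 4, near sampling noise. WT 2 lay at 3.62 and 3.67 from WT 3 and 4. How far the 6824 calls and their adjusted p-values rest on biological spread is therefore not settled. The split was 3514 higher and 2037 lower without the filter on low windows, and 2540 and 3607 with each position counted once. Without the 24313 windows in which a no-UV library exceeded the mean of its UV libraries, the count was 2257. A few events in these shallow libraries suffice for that, so the 24313 also reflects their depth. The count was 3006 with sequencing run as a block, 10463 with limma-voom and 15 after thinning to the shallowest library. It was 1291 without WT 4, 1493 without mutZn 3 and 1787 without mutZn 4.

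For D27aa against WT, the longest stretch with more D27aa events lay on the minus strand of chromosome 6 (122270001 to 122295000), where 5 windows held 796 ± 21.4 CPM in D27aa (n = 2), 379 ± 53.3 in WT (n = 3) and 1110 ± 22.7 in mutZn. The no-UV libraries held 687 CPM for D27aa and 506 for WT there, the latter above WT with UV. The longest stretch with fewer was 10 windows on the minus strand of chromosome 17 (80635001 to 80685000), with 1395 ± 142 CPM in D27aa, 2773 ± 222 in WT and 1205 ± 2.09 in mutZn. The WT no-UV library held 1640.5 CPM there, and the D27aa no-UV library, with its many positions of WT 4, held 2463. This stretch lies inside the chromosome 17 segment from 80585001 to 80690000 that was also lower in the WT-cell library, where the number of genomic copies was not measured. Also on the minus strand of chromosome 17, 3 windows (45700001 to 45715000) held 366 ± 10.5 CPM in D27aa, 886 ± 253 in WT and 711 ± 29.0 in mutZn. The no-UV libraries held 687 CPM for D27aa and 1090 for WT there.

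The largest increase of D27aa over WT in a single window was on the plus strand of chromosome 14 (48410001 to 48415000), at 203 ± 62.1 CPM against 7.52 ± 13.03 and a log2 fold change of 7.77 ± 1.05 (SE, adjusted p = 2.21e-12). It was 5.75 without WT 4, 4.85 after thinning and 9.00 with limma-voom, and all 5 WT events lay in WT 2. The WT no-UV library held 33.7 CPM there and the D27aa no-UV library no event. The plus-strand window of chromosome 15 at 72735001 to 72740000 followed, at 333 ± 159 CPM against 24.9 ± 41.0 and a log2 fold change of 6.42 ± 0.68 (adjusted p = 1.61e-11). The WT no-UV library held 1753 CPM in that window and the D27aa no-UV library 687 CPM, each more than the UV libraries of its group. The excess is therefore not shown to depend on UV. In that window the log2 fold change was 2.77 (adjusted p = 0.19) with each position counted once and 5.30 (adjusted p = 0.0553) with only the libraries of both groups (range over the alternatives 1.03e-157 to 0.19). Its log2 fold change was also 8.63 without WT 2, 4.53 without WT 4, 5.75 without D27aa 2, 3.92 after thinning, 8.68 with limma-voom and 9.10 within run 6. The minus-strand window of chromosome 11 at 97630001 to 97635000 held 193 ± 190 CPM against 7.85 ± 4.95 (log2 fold change 5.28 ± 0.53, adjusted p = 8.86e-11), and its log2 fold change was 1.88 (adjusted p = 0.0622) with each position counted once (range 3.82e-99 to 0.0622). It was also 5.92 without D27aa 1, 3.43 without D27aa 2, 4.32 after thinning, 5.88 with run as a block and 6.07 within run 6. D27aa had no event in 5 of the 8 lower windows named by the rule. These included chromosome 14 plus at 20915001 to 20920000, where WT held 32.5 ± 3.30 CPM and D27aa was at least 8.3-fold lower (adjusted p = 3.66e-05), chromosome 5 minus at 149015001 to 149020000 (20.7 ± 14.4 CPM in WT, at least 5.28-fold lower) and chromosome 14 plus at 20920001 to 20925000 (22.4 ± 0.523 CPM in WT, at least 5.7-fold lower). The chromosome 5 window did not pass with each position counted once (adjusted p = 0.0502) or with limma-voom (0.0619), in a range from 9.1e-07, and the D27aa no-UV library held 28.6 CPM (1 event) there. The bounds were at least 4.21-fold, 2.68-fold and 2.90-fold without D27aa 1 and 4.08-fold, 2.60-fold and 2.81-fold without D27aa 2, and the last window did not pass without WT 4 (0.0618), in a range from 8.64e-05. Within run 6 the 16 named windows had log2 ratios of 3.84 to 8.95 where D27aa was higher and of -7.86 to -3.52 where it was lower, with the direction fixed by the rule itself.

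In total, 819 of the 36173 windows passed the threshold between D27aa and WT, 489 higher and 330 lower in D27aa, and 38 of them had no event in one group. WT 2 lay nearer to D27aa than to WT 3 and 4 in the dispersion index, and the cause is not settled. The direction of the split changed to 632 higher and 876 lower without WT 2 and to 400 and 511 without the filter on low windows. The count was 491 with run as a block, 580 within run 6 (1 D27aa against 2 WT libraries), 476 with each position counted once, 194 with only the libraries of these groups, 233 without windows above their control and 35 after thinning. It was 1508 without WT 2, 241 without WT 4, 337 without D27aa 1 and 330 without D27aa 2, and limma-voom split its 1054 calls into 898 higher and 156 lower.

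The variants were also compared directly, since both comparisons above share the WT libraries. On the plus strand of chromosome 12 (110955001 to 110975000), 4 windows held 689 ± 15.95 CPM in mutZn and 333 ± 64.8 in D27aa (n = 2 each), and 2 windows on the minus strand of chromosome 10 (6970001 to 6980000) held 66.7 ± 1.34 and 14.5 ± 9.56. The no-UV libraries of mutZn and D27aa held 300.1 and 487 CPM in the first stretch and 30.01 and 0 in the second. On the plus strand of chromosome 17 (80635001 to 80650000), 3 windows were lower in mutZn, at 26.1 ± 1.35 CPM against 229 ± 40.2 in D27aa. They lie in the same chromosome 17 segment, which held 5104 and 5507 CPM on the minus strand in the mutZn libraries and 11861 and 12565 in the D27aa libraries. Of this, the strongest window (80600001 to 80605000) held 3662 ± 263 and 10343 ± 366 CPM. The no-UV libraries of mutZn and D27aa held 6137 and 7590 CPM in that window and 8073 and 10883 on the minus strand of the segment. With UV, mutZn lay below its own no-UV library in both. The minus strand from 80635001 to 80685000, which spans the 3 windows, held 1205 ± 2.09 CPM in mutZn and 1395 ± 142 in D27aa. The minus strand of this wider stretch thus showed no gap as large as that of the 3 plus-strand windows. Its level is not a measure of copies, since the no-UV libraries held 1395.5 CPM for mutZn and 2463 for D27aa, above the UV means. A difference in genomic copies is therefore not separated from one in crosslinking or RNA abundance there. D27aa had no event in the 8 higher windows named by the rule, and the bounds ranged from at least 3.58-fold to at least 6.42-fold (1.76-fold to 3.16-fold without D27aa 2). The highest bounds belonged to chromosome 13 minus at 104985001 to 104990000 (25.2 ± 8.58 CPM in mutZn, at least 6.42-fold, adjusted p = 0.00342), chromosome 2 plus at 104210001 to 104215000 (24.5 ± 3.23 CPM, at least 6.23-fold, adjusted p = 0.00324) and chromosome X minus at 106195001 to 106200000 (21.4 ± 0.037 CPM, at least 5.46-fold, adjusted p = 9.11e-04). None of these 3 passed with only the libraries of the 2 groups, at adjusted p-values of 0.407, 0.0855 and 0.0851, or with limma-voom, at 0.22, 0.104 and 0.0606. The ranges over the alternatives were 4.18e-07 to 0.407, 4.21e-06 to 0.146 and 1.58e-05 to 0.0851. Without mutZn 3 the first had an adjusted p of 0.0768 and the second of 0.0765, and without mutZn 4 the second had 0.146. Without D27aa 1 the 3 bounds were at least 3.26-fold, 3.17-fold and 2.78-fold, and without D27aa 2 at least 3.16-fold, 3.07-fold and 2.69-fold. The D27aa no-UV library held 57.3 CPM (2 events) in the chromosome 2 window, above mutZn with UV, and the mutZn no-UV library 45.02 CPM (3 events) in the chromosome X window. The first had 0.0727 with run as a block, and the third 0.0686 with each position counted once. The largest decreases in mutZn lay on chromosome 14 plus at 48410001 to 48415000 (0.975 ± 1.26 CPM against 203 ± 62.1, log2 fold change -8.20 ± 0.68, adjusted p = 9.46e-16), chromosome 4 minus at 63225001 to 63230000 (-7.75 ± 1.04, adjusted p = 1e-09, and 0.0536 after thinning in a range from 1.32e-80) and chromosome 9 plus at 11180001 to 11185000 (-6.46 ± 0.43, adjusted p = 7.31e-15). Without mutZn 3 these 3 log2 fold changes were -6.86, -6.86 and -5.45, and without mutZn 4 they were -11.32, -8.74 and -7.74. With run as a block they were -6.96, -6.16 and -5.14. The first was also -5.72 after thinning and -9.40 with limma-voom, the second -5.63 with each position counted once, and the third -4.99 with each position counted once, -7.11 with limma-voom and -5.03 within run 6.

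Between mutZn and D27aa, 873 of 36173 windows passed the threshold, 300 higher and 573 lower in mutZn. With each position counted once the split was 95 and 522. The count was 387 with run as a block, 436 within run 6 (1 library of each group, with the spread taken from WT 3 and 4), 1726 without the filter on low windows with the direction of the split changed to 1059 higher and 667 lower, 335 with only the libraries of these groups, 389 without windows above their control and 69 after thinning. It was 419 without mutZn 3, 448 without mutZn 4, 373 without D27aa 1 and 391 without D27aa 2.

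**Figure D2:**
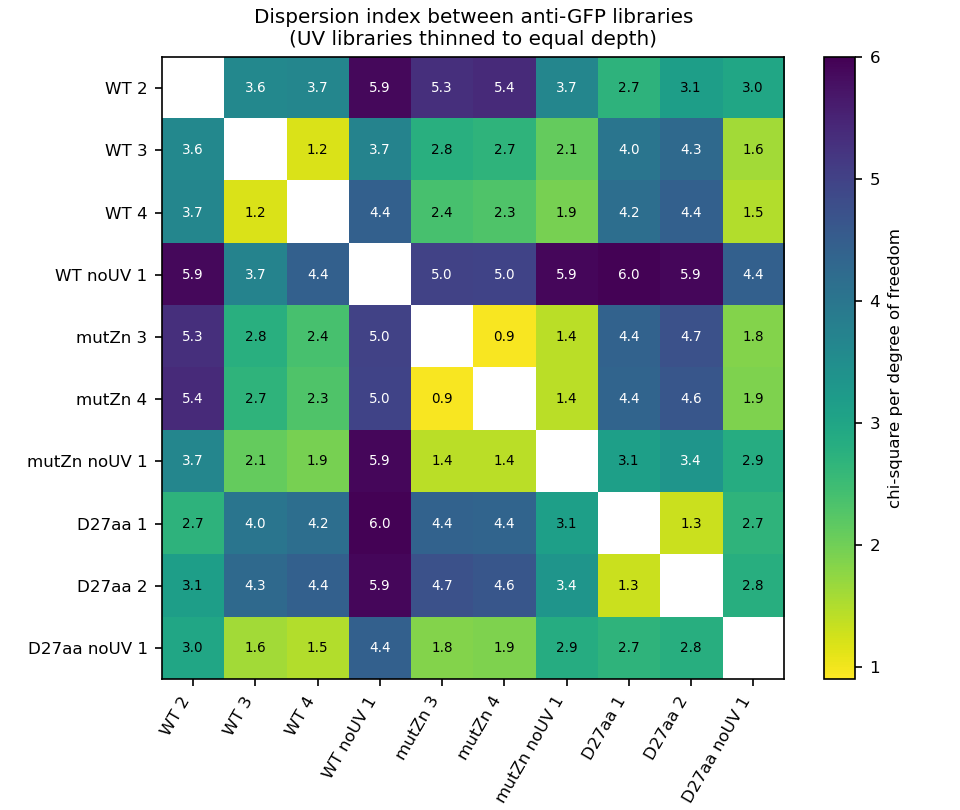
Dispersion index (chi-square per degree of freedom of window sums) for each pair of anti-GFP libraries, with UV libraries thinned to 221746 events and the shallower no-UV libraries as they were. The replicate pairs mutZn 3 and 4 (0.95), WT 3 and 4 (1.18) and D27aa 1 and 2 (1.30) lie near 1, and WT 2 lies at 3.62 and 3.67 from the other WT libraries.

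The polysomal and monosomal fractions of piCLIP were compared to ask whether SRSF7 crosslinked differently in them. The window with the most events in both was on the minus strand of chromosome 17 (80600001 to 80605000), with 6709 ± 3930 CPM in poly and 13020 ± 9768 in mono (n = 2 each). The window of chromosome 16 plus at 33045001 to 33050000 came second in both, with 6361 ± 195 CPM in poly and 8746 ± 3326 in mono. In a plus-strand window of chromosome 3 (85600001 to 85605000), mono held 6855 ± 2541 CPM and the polysomal IgG library 14250. None of 264 windows passed the quasi-likelihood test, 4 had an unadjusted p under 0.05, and limma-voom also called 0 with 4 unadjusted. A difference was not detectable with these libraries, since simulated changes of 8-fold were not recovered, and depth was not separated from the spread between replicates as the reason.

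With the anti-SRSF7 antibody, RRM_OE and endo_OE were each compared with GFP_OE. Their strongest windows were the same, on the plus strand of chromosome 17 (39980001 to 39985000) and the minus strand of chromosome 17 (80600001 to 80605000). The first held 21566 ± 5553 CPM in RRM_OE, 26555 ± 3820 in endo_OE and 17920 ± 10861 in GFP_OE (n = 2 each), and the second 17696 ± 3824, 16621 ± 720 and 17234 ± 7975. The no-antibody library held 65494 CPM in the first of them. On the minus strand of chromosome 19 (5795001 to 5800000) the values were 5605 ± 1950, 8483 ± 667 and 6999 ± 1971 CPM. These differences lay within the spread of GFP_OE. No window of 441 passed the quasi-likelihood test for RRM_OE against GFP_OE, with 10 unadjusted p-values under 0.05 and with 0 calls and 19 unadjusted by limma-voom. For endo_OE against GFP_OE 0 of 441 passed and 16 had an unadjusted p under 0.05, and limma-voom called 1 with 62 unadjusted. Simulated changes of 8-fold were recovered in 30.6% of windows for RRM_OE against GFP_OE.

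The endogenous protein was also mapped in WT cells, with 1 library and no replicate check. A segment was chosen after its values were seen. On the minus strand of chromosome 17, 21 windows (80585001 to 80690000) held 19777 ± 3930 CPM in the 6 anti-SRSF7 UV libraries of overexpressing cells, between 14187 and 25391, and 1278 CPM (270 events) in the WT-cell library. Whether these 6 libraries of GFP_OE, endo_OE and RRM_OE come from separate cultures is not settled. On the same strand the GFP_OE no-UV library held 29214 CPM (52 events) and the no-antibody library 9123 CPM (28 events). The excess over the WT-cell library is therefore not shown to be crosslinking of SRSF7. Plus-strand values of the same segment were 403 ± 88.0 CPM in the 6 libraries and 37.9 CPM (8 events) in the WT-cell library. A fit of endo_OE against endo_WT called 0 of 441 windows, with 34 unadjusted p-values under 0.05, and limma-voom called 0 with 86. With 1 endo_WT library, the other groups supplied the spread. The fit tested 10 windows of the segment, and the lowest adjusted p was 0.389.

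**Figure D3:**
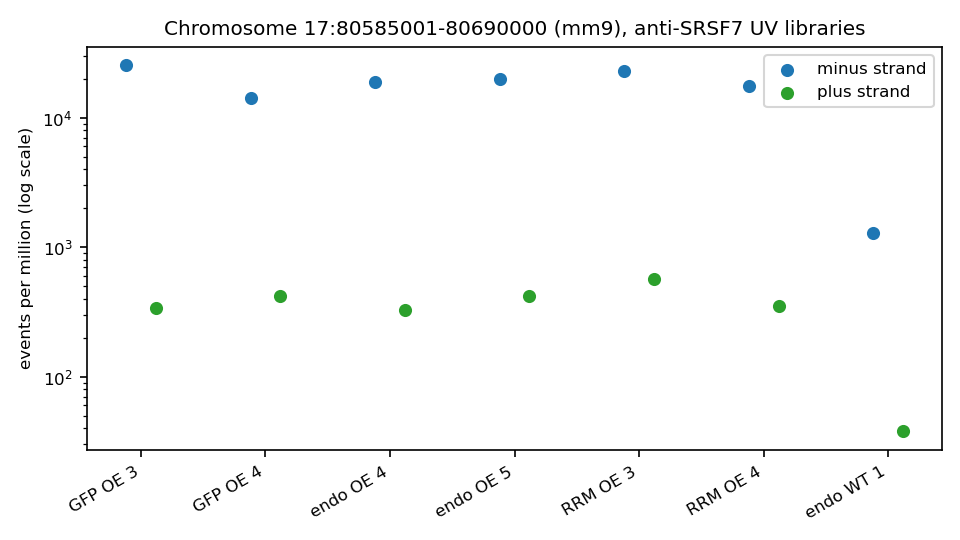
CPM (log axis) in the chromosome 17 segment 80585001 to 80690000 for each anti-SRSF7 UV library, minus strand in blue and plus strand in green. The WT-cell library (endo WT 1) lies lowest on both strands, at 1278 and 37.9 CPM.

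GFP_OE, precipitated with anti-SRSF7, was set against WT precipitated with anti-GFP, the same tagged protein reached with either antibody. GFP_OE was higher on chromosome 13 plus at 42510001 to 42515000, with 457 ± 593 CPM (n = 2) against 5.93 ± 6.62 (n = 3) and a log2 fold change of 7.35 ± 1.08 (SE, adjusted p = 0.00729). It was also higher on chromosome 4 minus at 4165001 to 4170000 (282 ± 249 CPM against 25.9 ± 28.7, log2 fold change 3.94 ± 0.76, adjusted p = 0.0325), on chromosome 1 minus at 173790001 to 173795000 (188 ± 236 against 12.1 ± 3.23, 3.77 ± 0.77, adjusted p = 0.0403) and on the mitochondrial minus strand at 5001 to 10000 (232.5 ± 94.3 against 28.7 ± 10.5, 3.30 ± 0.53, adjusted p = 0.0108). The no-UV library of GFP_OE held 562 CPM in the mitochondrial window. GFP_OE had no event on chromosome 13 plus at 23355001 to 23360000, where WT held 67.2 ± 54.6 CPM, at least 13.4-fold more (adjusted p = 0.0341). It had 1 event each on chromosome 8 minus at 115505001 to 115510000 and chromosome 11 plus at 3200001 to 3205000, where WT exceeded it 25.4-fold (95% counting interval 4.52 to 1008, adjusted p = 0.0198) and 20.4-fold (3.62 to 811, adjusted p = 0.0432). The log2 fold change of the first window was 6.4 without WT 4, and that of the chromosome 4 window was 4.59 without WT 2, 3.26 without WT 3 and 3.10 without GFP_OE 3. With each position counted once these windows had 5.21 and 3.00. The first had 6.63 without the filter and 6.27 with limma-voom, and the chromosome 1 window 2.92 without the filter and 2.03 with limma-voom. The bound on chromosome 13 at 23355001 was at least 2.84-fold without GFP_OE 4. The single GFP_OE event lay in GFP_OE 4 on chromosome 8 and in GFP_OE 3 on chromosome 11. Without WT 3 the adjusted p was 0.841 for the first of these windows, 0.871 for the chromosome 4 window and 0.871 for the chromosome 11 window, and without WT 4 it was 0.651, 0.738 and 0.753. The chromosome 8 and 11 windows had 0.0812 and 0.0658 without GFP_OE 3 and 0.53 and 0.601 without GFP_OE 4. With limma-voom the chromosome 1, chromosome 13 (23355001), 8 and 11 windows did not pass, at 0.141, 0.392, 0.118 and 0.181, and the chromosome 4 window had 0.134 after thinning.

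Of 9899 windows, 133 passed the threshold between the antibodies, 106 higher and 27 lower in GFP_OE, and with library totals alone the split was 99 and 55. The groups lie in separate sequencing runs, so run and antibody cannot be told apart. The count was 217 without the filter on low windows, 80 with each position counted once, 52 without windows above their control, 0 after thinning with 87 unadjusted p-values under 0.05, and 1115 with limma-voom. It was 393 without WT 2, 0 without WT 3 (231 unadjusted), 0 without WT 4 (304 unadjusted), 37 without GFP_OE 3 and 18 without GFP_OE 4.

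The authors' summed peak lists held 2045481 peak nucleotides for WT, 2246120 for mutZn, 34759 for D27aa and 20437 for piCLIP. Of these, 21.9% of the mutZn nucleotides (95% interval 21.9% to 22.0%), 54.8% of the D27aa nucleotides (54.2% to 55.3%) and 32.7% of the piCLIP nucleotides (32.1% to 33.4%) were also WT peak nucleotides on the same strand. Conversely, 24.1% of the WT peak nucleotides were shared with mutZn, 0.931% with D27aa and 0.327% with piCLIP. Within 30 nt of a WT peak lay 56.6%, 76.8% and 58.3%, and on the opposite strand 0.0113%, 0.023% and 0.0245%. The lists came from different depths and have no replicates, so the shares are not comparable as changes. The header of the WT list names 4 source experiments, and 68.02% of its nucleotides had no event in the 3 WT libraries, so the list also holds data of a library not analysed here.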

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

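The measures in this part were chosen after the library totals had been seen, and none of the differences was tested, since each no-UV group had 1 library. Of 4 measures screened in 2 families of libraries, a pair is listed because every UV library of one group lay on one side of its no-UV library and every UV library of another group on the other side.

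The share of events on the mitochondrial chromosome was lower with UV than without it for WT, by a difference of -0.9115 percentage points. For mutZn the difference was 0.02893 points, and the UV mean lay inside the counting interval of the no-UV share (Wilson 95% interval 0.355% to 0.451%, 267 of 66690 events), so mutZn is not shown to move. It was 0.0461 points without mutZn 3 and 0.0118 without mutZn 4.

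The share of events on the minus strand was higher with UV for WT, by 0.6128 points, and for D27aa, by 1.027 points. The D27aa no-UV library, with its many positions of WT 4, is not a settled background. For WT, the no-UV library lay in run 4 and the UV libraries in runs 5 and 6. UV and run therefore cannot be told apart for WT in either measure. The WT difference was 0.313 points without WT 2, with the UV mean then inside the counting interval of the WT no-UV share (49.94% to 50.6%). For mutZn it was -0.1489 points, again inside the counting interval of the no-UV share (49.94% to 50.7%), and it was -0.203 points without mutZn 3 and -0.0951 without mutZn 4. No explanation of these differences was tested.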

How the results depend on the processing

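Fits with limma-voom, with sequencing run as a block and within a run were chosen after the results had been seen, and the other alternatives were planned. Of 126 recomputed counts and shares, 77 stayed within their limits and 49 moved. A count stayed within its limits when it changed by at most 1.5-fold, so a 0 that remained 0 was among the 77. That was so in most alternatives of poly against mono, RRM against GFP and endo against GFP. Simulated 8-fold changes were recovered in no window for poly against mono and in 30.6% for RRM against GFP. The peak shares under a minimum overlap could not move, since peaks are single nucleotides. These entries say little about stability, so the 77 overstates it. Of 287 recomputed single windows, 254 kept their direction and their side of the threshold, 33 kept the direction and lost the threshold, and 0 changed direction. These windows were chosen for large folds and full separation of the groups, so a change of direction was hardly possible.

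For mutZn against WT the count of 6824 became 15 after thinning, where 3058 windows were tested, 2257 without windows above their control, 10463 with limma-voom and 3006 with run as a block. Leaving out each library gave 1291 to 9841 (1291 without WT 4, 1493 without mutZn 3, 1787 without mutZn 4). For D27aa against WT the count of 819 became 476 with each position counted once, 35 after thinning, 194 with only these libraries, 233 without windows above their control and 491 with run as a block. Leaving out each library gave 241 to 1508 (241 without WT 4, 1508 without WT 2, 337 without D27aa 1, 330 without D27aa 2). For mutZn against D27aa the count of 873 became 1726 without the filter, 69 after thinning, 335 with only these libraries, 389 without windows above their control, 387 with run as a block and 436 within run 6, and leaving out each library gave 373 to 448 (419 without mutZn 3, 448 without mutZn 4, 373 without D27aa 1, 391 without D27aa 2). For anti-SRSF7 against anti-GFP the count of 133 became 217 without the filter, 80 with each position counted once, 0 after thinning with the quasi-likelihood test (87 unadjusted), 52 without windows above their control and 1115 with limma-voom. Leaving out each library gave 0 to 393 (393 without WT 2, 0 without WT 3, 0 without WT 4, 37 without GFP_OE 3, 18 without GFP_OE 4). Thinning and leaving out windows reduce the events or windows tested. For the other changes the cause was not tested.

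For poly against mono no alternative called a window with the quasi-likelihood test or limma-voom, with 0 to 12 unadjusted p-values under 0.05 where a library was left out. RRM against GFP gave 0 to 1 when a library was left out (1 without GFP_OE 3), and endo against GFP gave 1 with limma-voom. The median log2 fold change of all windows moved from -0.57 to -0.43 with median-of-ratios scaling and to -0.78 with library totals for poly against mono, from -0.23 to -0.05 with library totals for RRM against GFP, and from 0.03 to -0.11 with library totals for anti-SRSF7 against anti-GFP.

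With the replicate number as a block, mutZn against WT gave 9589 calls, poly against mono 0 (5 unadjusted) and RRM against GFP 1. The same-numbered libraries, 2 pairs in each comparison, as numbered in the titles and not in the file headers, had deviations correlated at -0.02, 0.45 and 0.33, which 2 pairs are too few to read as pairing. Same-numbered RRM_OE and GFP_OE libraries also shared a sequencing run, and all piCLIP libraries lay in 1 run.

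The share of peak nucleotides that were WT peak nucleotides was 56.6% for mutZn, 76.8% for D27aa and 58.3% for piCLIP within 30 nt, 23.1%, 63.7% and 29.2% above the median score, and 0.0113%, 0.023% and 0.0245% on the opposite strand. A minimum overlap of 50% moves nothing, since peaks are single nucleotides. The D27aa no-UV total was 9.71% of its UV mean with each position counted once. Alternatives on gene models, pentamers and transcript regions and the Wald test of another package were not run. The piCLIP and anti-SRSF7 comparisons tested 264 and 441 windows, and depth and the spread between replicates were not separated as limits.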

Other observations

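The test for extra copies was written before its result was seen, and all the other tests in this part were chosen after theirs. The strongest windows were shared by most groups. The minus-strand window of chromosome 19 at 5795001 to 5800000 held 7642 ± 1153 CPM in WT (SD, n = 3), 7762 ± 69.4 in mutZn (n = 2), 8654 ± 111 in D27aa (n = 2) and 12104 in endo_WT (n = 1). The minus-strand window of chromosome 17 at 80600001 to 80605000 held 11225 ± 3589 CPM in WT, 10343 ± 366 in D27aa and 3662 ± 263 in mutZn. The no-UV libraries held 7371, 7590 and 6137 CPM there. With UV, mutZn thus lay below its own no-UV library, and its low value is not shown to be less crosslinking. The plus-strand window of chromosome 11 at 68885001 to 68890000 was among the 5 strongest in endo_OE (8177 ± 188 CPM, n = 2) and in endo_WT (7041 CPM).

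The plus strand of chromosome 14 at 20915001 to 20930000 held 366 events in the WT libraries, 10 in mutZn and 0 in D27aa, and 4 in the WT no-UV library. Replicates of every group differed beyond sampling noise, with dispersion indices of 1.11 for mutZn, 1.30 for D27aa, 1.14 to 2.11 for WT, 5.22 for GFP_OE, 6.46 for RRM_OE, 3.03 for endo_OE, 8.62 for mono and 22.6 for poly.

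The D27aa no-UV library shared 8932 of its 31512 positions (28.3%) with WT 4 at the same nucleotide. The ratio of same-nucleotide pairs to pairs 1 or 2 nt away was 5.168, the highest of 45 anti-GFP pairs (next 2.78), against 1.10 to 1.31 for the 3 UV libraries of other runs and 0.849 and 1.125 for the no-UV libraries of mutZn and WT. Depth of WT 4 is argued against by libraries deeper than WT 4, which reached at most 1.19. Both libraries lay in run 6 and their barcodes differ at 1 of 4 bases, and cDNAs of WT 4 may be present in the no-UV library. How they came there is open. The same-run pair GFP_OE 4 and endo_WT, also 1 base apart, had a ratio of 2.66 within the 1.85 to 2.87 of all anti-SRSF7 UV pairs. Same-run pairs with 21 to 37 shared positions had 5.25 at 1 base, 10.22, 11.38 and 13 at 2 bases, 4.13 at 3 bases and 3.23 at 4 bases. No biological explanation was tested.

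WT 2 lay nearer to D27aa than to WT 3 and WT 4. After thinning, its lowest dispersion index against WT 3 and 4 was 3.617, so depth does not account for it. The index against D27aa 2, of another run, was 3.139, which argues against run as the cause. The lowest index of WT 2 against a D27aa library was 2.065 times that between the D27aa libraries, known from 1 pair. Its same-nucleotide ratios were 2.55 and 2.44 with D27aa, 2.78 between the D27aa libraries, and 1.39 and 1.32 with WT 3 and 4. These ratios were not matched for depth and cannot decide on a mislabelled library, since the deep replicate pairs WT 3 and 4 and mutZn 3 and 4 had 1.43 and 1.37. In windows chosen for mutZn against WT, chromosome 12 plus at 12260001 and chromosome 14 plus at 20915001, every WT library held at least 113.7 and 29.6 CPM. D27aa held at most 2.66 CPM in the first and no event in the second, which argues against WT 2 being wholly a D27aa library. A mixture of RNA or a difference between the cultures was not tested.

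The chromosome 17 segment at 80585001 to 80690000 was 15.5-fold lower in endo_WT, from WT cells, than in the 6 UV libraries of overexpressing cells, and its ends were set from that ratio. The GFP_OE no-UV and no-antibody libraries, also from overexpressing cells, held 29214 and 9123 CPM there on the minus strand (52 and 28 events). The difference is thus not shown to be crosslinking. Of the 6 UV libraries 5 had fewer events than endo_WT, which argues against depth, and within its own run the lowest ratio was 11.11, which argues against run. Of the segment's events in overexpressing cells 2.284% lay on the plus strand, against at most 1.08% in strong windows elsewhere and 0 of 11338 in its own strongest window, which argues against opposite-strand reads. The plus-strand ratio was 10.63 (95% interval 5.33 to 24.8), while 707 blocks of the same length with 150 to 600 events reached at most 3.84, so extra copies of a genomic segment in the overexpressing cells may explain the pattern. WT cells had 1 library, the plus strand 8 events there, and blocks beside the segment held 46 against 1 and 23 against 1 plus-strand events, so its ends are not settled.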
